A study of Cucumis sativus and Botrytis cinerea with 3 samples.

How the data were processed

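RNA from 3 samples was sequenced on an Illumina platform, per the series' design text, with libraries made with the TruSeq RNA kit from Trizol-extracted total RNA, per the labels' protocols. The samples were cucumber leaf alone, Botrytis cinerea mycelium alone and inoculated cucumber leaf, 1 library each. The groups were taken from the protocol label of each sample, and the single-organism samples were read as uninoculated because only the third sample's labels name an inoculation.

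The authors deposited 2 tables of RPKM, 1 per organism, each with 1 column for the single-organism library and 1 for the inoculated leaf, so that both tables share the inoculated leaf. Per the submitters' processing notes, Bowtie 0.12.2 was used. Those notes also name a mouse genome build, which belongs to neither organism. The genome builds, the gene annotation, the counter, the handling of reads that match both organisms or several genes, and the use of strand are not given in the sources used here. How the genes without a Csa, B0510 or EFBFUG prefix were defined is not given either. Reads shared between near-identical genes, between overlapping genes or between the organisms could therefore be split in ways that the values do not show. All 4 columns were used, and 0 columns were left out.

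The depth was recovered from the values. An RPKM of whole reads is a constant times the reads, divided by the library total and the gene length, so the constant divided by the value of a gene with 1 read is the product of total and length. The 300 lowest values above 0 of each column were used, and among these the ones whose product was whole. The commonest greatest common divisor over their pairs gave a base total. A base total can hold a factor common to the gene lengths, so the smallest total not below the sum of the recovered reads was taken, with the same factor in both columns of a table. With these totals 100% of the values above 0 were ratios of 2 whole numbers, with a length of at most 40000 and a relative error under 3e-14. For Botrytis the factor was 3, and for cucumber it was 1. The totals, and with them the share of Botrytis reads in the inoculated leaf, rest on that rule. Reads and lengths come back only up to a factor common to both columns, so the reads per gene are minimum numbers. They summed to 88.8% of the total in both cucumber columns and to 87.3% in both Botrytis columns. The intervals based on them are therefore wide rather than narrow. Whether the unit was a read or a read pair, and whether a total held reads on genes or all mapped reads, is not given, and amplified reads are not independent molecules, so the intervals cover counting error only. Fold intervals are exact conditional binomial (Clopper-Pearson) intervals at 95%.

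Changes are log2((RPKM + 1)/(RPKM + 1)), inoculated leaf over the single-organism library, with a pseudocount of 1. Genes with a mean of at least 1 RPKM over the 2 libraries were counted as at least 2-fold, 4-fold or 8-fold higher or lower. Since each group had 1 library, no model was fitted and no p-value computed. Genes listed at 0 in 1 library were counted where the other library had at least 5 RPKM, and no fold is given for them. The following choices were fixed before the data were examined: the groups, the pseudocount, the filter, the 2-fold bound, the floor of 5 RPKM, and the alternatives. The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 RPKM, rescaling each library to the same sum, centring on the median, upper-quartile scaling and a floor of 1 RPKM. The 4-fold and 8-fold bounds, the counting interval, the identifier groups, the expression classes, the shares of reads and the 100 most abundant genes were chosen after seeing the data.

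The rule for named genes, fixed beforehand, took genes with a product name by the size of their log2 change, by list and by abundance. For genes without a name it allowed at most 2 identifiers that were higher and 2 that were lower per organism. Its order for named genes was applied to them, the greatest log2 change among genes past the filter and above 0 in both libraries. A set of 28 gene lists defined by product names had also been fixed. The unit was as the design assumed. The reference table, of the assembly Cucumber_9930_V3, held 23999 cucumber genes under other identifiers, and 0 cucumber identifiers matched. It is a cucumber table, so Botrytis identifiers could not match it, and no Botrytis reference was used. With these sources no gene list could be tested and no gene could be given a product or coordinates. Chromosome numbers and the order of genes were read from the identifiers themselves.

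The scripts were tested on simulated tables built from the recovered totals and from levels proportional to the real genes' means. Gene lengths were drawn at random, so the simulated RPKM values did not equal the real means. Simulated Botrytis lengths were multiples of 3, except for genes with neither the B0510 nor the EFBFUG prefix. Each simulated total was the sum of the reads on genes. The simulated totals came back exactly in both organisms. Since the lengths were built this way, that does not test the division of the real Botrytis total by 3. Recovered reads equalled the simulated ones in 83.6% of the 21159 cucumber genes with reads among 23923 simulated and in 76.1% of the 10825 Botrytis genes with reads among 11629 simulated, and every simulated count was a multiple of the recovered one. The changed genes numbered 50 per fold size. They were drawn from genes with a real mean of at least 1 RPKM, and the filter was not applied to their simulated values. In the cucumber simulation, 94% of genes raised 3-fold, 70% lowered 3-fold, 100% raised 8-fold and 92% lowered 8-fold passed the 2-fold bound. In the Botrytis simulation these shares were 86%, 72%, 100% and 92%, and 0.635% of unchanged genes passed the bound from counting error alone, against 0% in the cucumber simulation. The simulation holds no variation between samples, and its lengths and levels are not those of the real genes. These shares are therefore not detection or error rates for the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.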

Results

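Messenger RNA was sequenced from 3 libraries to ask how the transcripts of a plant and of a fungus change when the fungus grows on the plant. The plant is cucumber, and the fungus is Botrytis cinerea, a grey mould that kills the plant cells it feeds on. The first library came from the leaf of 4-week-old cucumber that the labels do not describe as inoculated. The labels call this sample and the fungal one anti-infection, a term they do not define. The second came from Botrytis mycelium, the thread-like body of the fungus, aged 96 h. The third came from cucumber leaf 96 h after inoculation with Botrytis and held RNA of both organisms. Each group had 1 library, so no difference below has a replicate check and no p-value is given. Intervals cover counting error only. Expression is given as RPKM, the reads on a gene scaled by the length of the gene and by a total of the library for that organism. The totals recovered from the RPKM values were 29304492 reads for cucumber in the leaf alone and 21643221 for Botrytis in the mycelium. For the inoculated leaf they were 48154374 for cucumber and 2087047 for Botrytis. Whether these totals hold reads on genes or all mapped reads of an organism is not given in the sources used here. The gene identifiers are not paired with names or products in the files. Of the 23923 cucumber identifiers, 0 matched the cucumber gene table used as a reference. No Botrytis reference was used for the 11629 Botrytis identifiers. Genes are therefore described by group, and at most 2 identifiers per direction are printed for each organism. No function is stated for them.

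In the inoculated leaf, the Botrytis total was 4.15% of the sum of the cucumber and Botrytis totals (95% exact Clopper-Pearson interval 4.15 to 4.16%). There were 23.1 cucumber reads for each Botrytis read. This share rests on a Botrytis total that was divided by 3, a factor common to the gene lengths. Undivided, the Botrytis total would be 6261141 and the share 11.5%. The recovered Botrytis reads would then sum to 36.9% of the total in the mycelium and 35.5% in the inoculated leaf. After the division they summed to 87.3% in both. The Botrytis profile in the leaf therefore rested on fewer reads than the mycelium profile. Of the 11629 Botrytis genes listed, 10203 had a value above 0 in the inoculated leaf and 10925 in the mycelium. Of the 704 Botrytis genes listed at 0 in the mycelium, 652 were also listed at 0 in the inoculated leaf.

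The first comparison asked which cucumber transcripts differed between inoculated leaf and leaf alone. A set of 803 cucumber genes at least 4-fold higher in the inoculated leaf took 24.6% of its recovered cucumber reads, against 2.38% in the leaf alone. A set of 1543 genes at least 4-fold lower took 1.55% of the cucumber reads in the inoculated leaf, against 15.5% in the leaf alone. Both sets were chosen on these 2 libraries. Among 17003 cucumber genes with a mean of at least 1 RPKM, 1912 (11.2%) were at least 2-fold higher and 4474 (26.3%) at least 2-fold lower, and 10617 (62.4%) differed by less than 2-fold. The median log2 change over these genes was -0.34 (5th to 95th percentile -2.59 to 1.94). Relative to that median, 2727 genes were at least 2-fold higher and 3100 at least 2-fold lower, so that 46.8% of the changed genes were higher, against 29.9% without the centring. Centring brings the sides toward even by construction. Lower genes were the larger side at the 2-fold bound under each scaling tried, with 53.2% of the changed genes after centring, 62.4% with upper-quartile scaling, 70.1% as deposited and 73.5% with each library rescaled to the same sum. At the 8-fold bound 359 genes were higher and 532 lower as deposited, but 466 higher and 364 lower after centring, and 206 higher and 162 lower with a pseudocount of 5. Counts of genes past a fold use the log2(RPKM + 1) scale, which understates changes of low genes, while folds and ratios printed for single genes are ratios of the RPKM values.

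**Figure D1:**
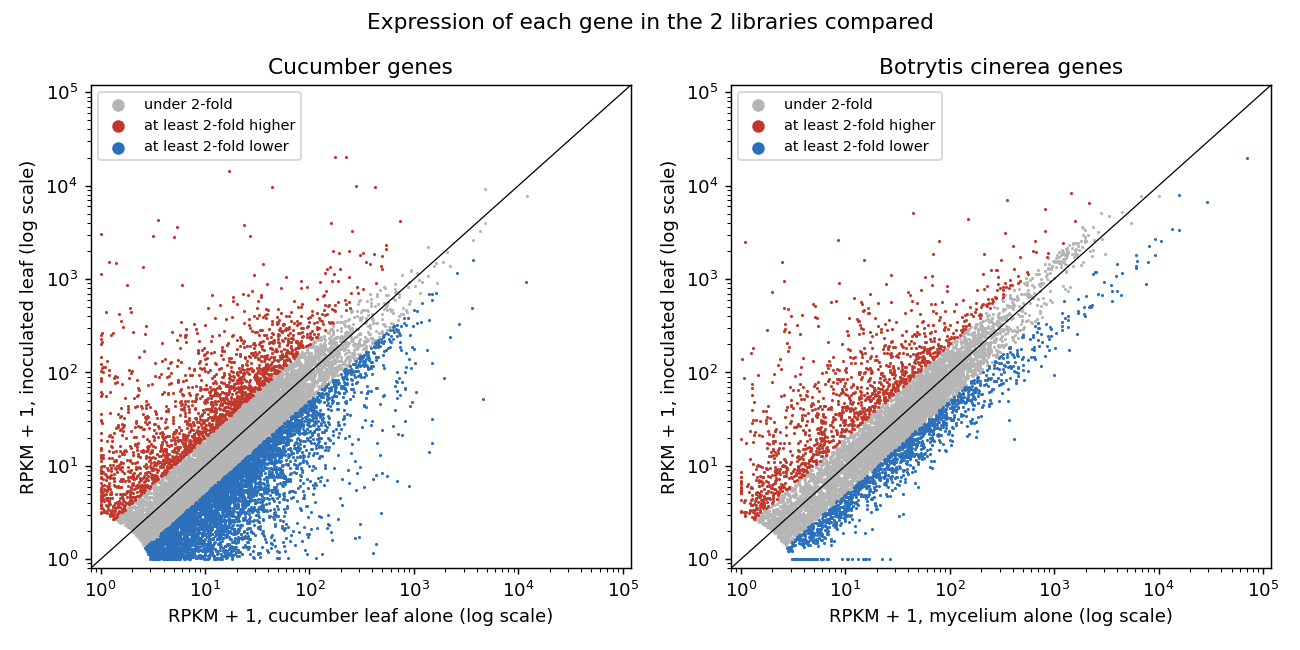
RPKM + 1 of each gene in the inoculated leaf against the single-organism library, on log axes, for cucumber (left) and Botrytis (right); each point is 1 gene with a mean of at least 1 RPKM, and the line marks equal values. Cucumber has 1912 genes at least 2-fold higher (red) and 4474 lower (blue), while Botrytis has 1298 and 1360; at the 8-fold bound Botrytis has 242 genes above the line and 22 below it.

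The cucumber genes named here had the greatest positive and negative log2 changes among genes above 0 in both libraries. Csa5G487690 was at 0.209 RPKM in the leaf alone and 1535 RPKM in the inoculated leaf, a ratio of 7353 (95% counting interval 2035 to 60716, from at least 2 and 24164 reads). Csa3G142960 was at 2.56 RPKM in the leaf alone and 4289 RPKM in the inoculated leaf, a ratio of 1677 (interval 1118 to 2646). In the other direction, Csa4G325520 was at 409 RPKM in the leaf alone and 0.157 RPKM in the inoculated leaf, 2607-fold lower (interval 891 to 12645, from at least 4759 and 3 reads). Csa1G228960 was at 435 RPKM in the leaf alone and 0.466 RPKM in the inoculated leaf, 932-fold lower (interval 621 to 1470).

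The most abundant cucumber transcripts differed between the libraries. Of the 100 most abundant cucumber genes in the leaf alone, 64 were at least 2-fold lower in the inoculated leaf and 1 was at least 2-fold higher, and their median went from 928 to 353 RPKM. Of the 100 most abundant in the inoculated leaf, 60 were at least 2-fold higher than in the leaf alone and 6 at least 2-fold lower. The 2 lists shared 32 genes. Choosing genes by their level in one library favours a lower level in the other. The most abundant cucumber gene of the inoculated leaf stood at 20443 RPKM there and at 221 RPKM in the leaf alone, 92.7-fold higher. The 100 most abundant genes held 30.1% of the summed RPKM in the inoculated leaf and 20.2% in the leaf alone. A further 32 cucumber genes were listed at 0 in the leaf alone and at 5 RPKM or more in the inoculated leaf, the highest at 3046 RPKM, and 13 showed the opposite, the highest at 17.1 RPKM. The leaf alone had the smaller recovered cucumber total, and of these 2 libraries only the inoculated leaf held Botrytis RNA. Botrytis reads assigned to cucumber genes cannot be told apart here without sequences.

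Cucumber genes with a low mean over the 2 libraries were lower in the inoculated leaf more often than those with a moderate mean. That mean includes the inoculated leaf, so a gene's own change helps set its class. Of 2207 genes with a mean of 1 to 3 RPKM, 31.7% were at least 2-fold lower and 8.34% at least 2-fold higher, with a median log2 change of -0.58. Of 4275 genes at 3 to 10 RPKM, 33.1% were lower and 8.75% higher. At 30 to 100 RPKM the shares were closer, with 18.7% of 3633 genes lower and 15.6% higher and a median of -0.09. At 100 to 300 RPKM, 25.6% of 1071 genes were higher and 21.8% lower. Of the 324 genes at 300 RPKM and above, 34.6% were lower and 26.2% higher.

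**Figure D2:**
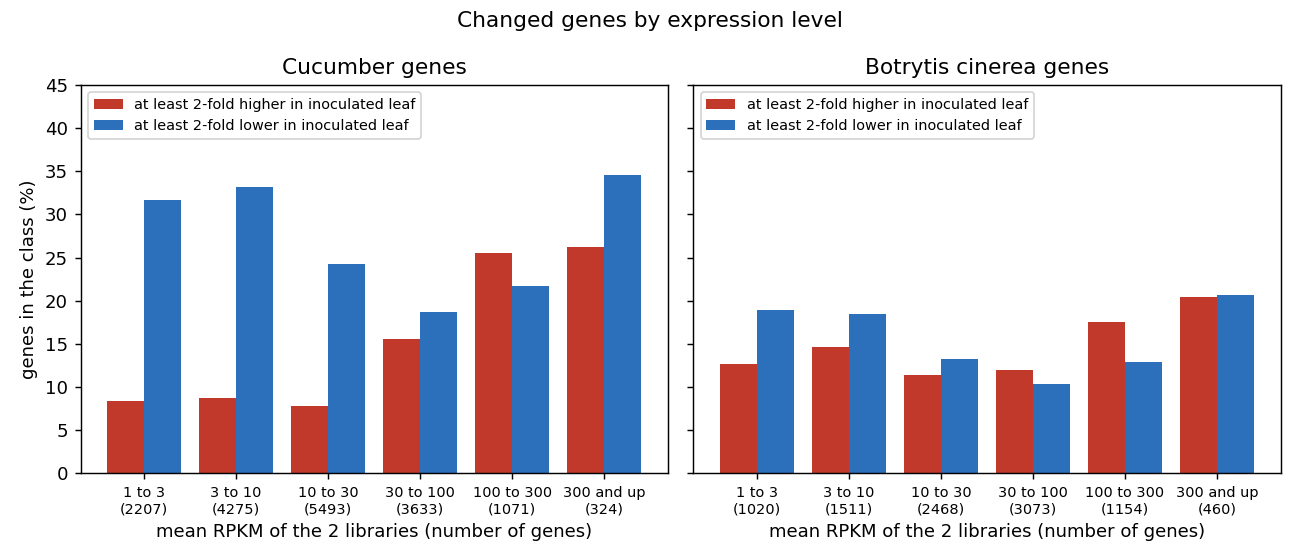
Share of genes (percent, vertical axis) at least 2-fold higher (red) or lower (blue) in the inoculated leaf, by mean RPKM of the 2 libraries, for cucumber (left) and Botrytis (right), with the number of genes per class under each pair of bars. In cucumber 31.7% of the 1 to 3 RPKM class were lower and 8.34% higher, and in Botrytis 18.9% of that class were lower and 12.6% higher.

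The shares of changed cucumber genes were also counted by the form of the identifier. By the published numbering of this gene set, the digit after Csa gives the chromosome. The share at least 2-fold higher ran from 9.95% of 2393 genes on chromosome 1 to 13.6% of 2001 genes on chromosome 4. The share at least 2-fold lower ran from 24.3% on chromosome 4 to 28.0% of 1994 genes on chromosome 2. Identifiers beginning CsaUNG, 87 genes with no chromosome number, had 17.2% higher and 25.3% lower. The 535 genes without the Csa prefix had 9.72% higher and 26.5% lower.

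The second comparison asked which Botrytis transcripts differed between fungus growing in the leaf and mycelium alone. Large differences were mostly higher values in the leaf: 534 Botrytis genes were at least 4-fold higher and 212 at least 4-fold lower, and 242 were at least 8-fold higher against 22 at least 8-fold lower. The 534 genes took 14.4% of the Botrytis reads in the inoculated leaf and 1.52% in the mycelium. The 212 took 2.09% in the inoculated leaf and 10.4% in the mycelium. At the 2-fold bound the numbers were near each other, with 1298 genes (13.4%) higher and 1360 lower among 9686 with a mean of at least 1 RPKM, and which of the 2 was larger changed with the scaling, the pseudocount and the filter. After each library was rescaled to the same sum, 1432 were higher and 1198 lower. The median log2 change was -0.09. Of 1020 Botrytis genes with a mean of 1 to 3 RPKM, 18.9% were lower and 12.6% higher, and of 1154 at 100 to 300 RPKM, 12.9% were lower and 17.5% higher. Across genes, which are not independent replicates, log2(RPKM + 1) of the 2 Botrytis libraries had a Pearson r of 0.844, and that of the 2 cucumber libraries 0.722.

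The Botrytis gene with the greatest positive log2 change among those above 0 in both libraries was B0510_171, at 0.0987 RPKM in the mycelium and 2477 RPKM in the leaf. Its ratio of 25086 rests on at least 1 read in the mycelium and has a 95% counting interval of 4498 to 991235. B0510_3095 was at 1.47 RPKM in the mycelium and 1512 RPKM in the leaf, a ratio of 1026 (interval 737 to 1476). With the same limit, which leaves out genes listed at 0 in the inoculated leaf, the greatest negative change was that of B0510_2550. It was at 413 RPKM in the mycelium and 18.1 RPKM in the leaf, 22.7-fold lower (interval 12.3 to 47.5, from at least 2359 and 10 reads). B0510_7381 was at 370 RPKM in the mycelium and 29.7 RPKM in the leaf, 12.4-fold lower (interval 9.13 to 17.4). Cucumber reads assigned to B0510_171 or B0510_3095 cannot be told apart from fungal reads without sequences, and the intervals do not cover this.

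The abundant Botrytis transcripts were shared more widely between the libraries than those of cucumber. The 100 most abundant genes of the mycelium and of the inoculated leaf had 60 genes in common. Of the mycelium's 100, 45 were at least 2-fold lower in the leaf and 3 at least 2-fold higher. Of the leaf's 100, 22 were at least 2-fold higher and 10 at least 2-fold lower than in the mycelium. The same gene led both libraries, at 70129 RPKM in the mycelium and 19837 RPKM in the leaf, 3.54-fold lower. The 10 most abundant genes held 18.7% of the summed RPKM in the mycelium and 8.66% in the leaf. Some genes were listed at 0 in one library and at 5 RPKM or more in the other. Of these, 8 had their value in the leaf, 4 of them with EFBFUG identifiers. The other 16 had it in the mycelium, 11 of them with EFBFUG identifiers. In the leaf, a short gene can pass 5 RPKM on a recovered minimum of 1 read. The EFBFUG genes past the filter had a median minimum length of 95 and a median of 1 recovered read there. These counts therefore do not separate presence or absence in the leaf from counting error.

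Among the Botrytis identifier groups, the 8767 B0510 genes had 13.3% at least 2-fold higher and 13.4% at least 2-fold lower. The 812 genes with neither prefix had 10.6% higher and 18.5% lower. The 107 EFBFUG genes had 40.2% higher and 31.8% lower, with an SD of the log2 change of 1.96 against 1.18 for the B0510 genes. Their median was 1 recovered read per gene in the inoculated leaf, against 64 for the B0510 genes, and differences resting on so few reads can come from counting error. Counting only genes whose fold had a 95% counting interval that left out 1 gave 1197 higher and 1165 lower Botrytis genes, and 1904 higher and 4465 lower cucumber genes.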

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

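No direction was reversed under the alternatives tried for the 8 genes named and for the correlations of adjacent genes. The 8 genes were chosen for their large changes, which such settings could not reverse, so for them this is no check. Of 38 alternative values of the 2-fold counts, the counts of genes listed at 0 and the read share, 30 stayed within 1.5 times the reported count or, for the share, its counting interval; of 126 other values 104 did so by the same kind of bound and 22 moved. With a pseudocount of 5, the genes at least 2-fold lower numbered 2702 in cucumber, against 4474, and 794 in Botrytis, against 1360; a larger pseudocount shrinks the change of low genes by construction. With a floor of 1 RPKM in place of 5, the genes listed at 0 in the other library numbered 89 in inoculated leaf and 77 in leaf alone for cucumber, and 28 in inoculated leaf and 164 in mycelium for Botrytis. The Botrytis share of the inoculated leaf was 4.09% from the recovered minimum reads and 11.5% with the Botrytis total not divided by 3, both settings added after seeing the data. At the 4-fold and 8-fold bounds, added after seeing the data, counts were made under the same pseudocounts, filters and scalings. The cucumber genes at least 4-fold lower ran from 611 to 2244 and those at least 4-fold higher from 509 to 1045; those at least 8-fold lower ran from 162 to 1156 and those at least 8-fold higher from 206 to 519, and the larger side turned from lower to higher after centring and with a pseudocount of 5. The Botrytis genes at least 4-fold lower ran from 92 to 379, those at least 4-fold higher from 372 to 672, those at least 8-fold lower from 4 to 87 and those at least 8-fold higher from 147 to 341. No paired analysis was possible because each group had 1 library, and no library could be left out for the same reason. The alternatives planned for the gene lists were not run, since no list could be matched. In the inoculated leaf 1426 Botrytis genes were listed at 0, against 704 in the mycelium. Thinning the mycelium's recovered reads to the total of the inoculated leaf left 1592 to 1677 genes at 0 in 100 draws, added after seeing the data; the recovered reads are minimum numbers, which raises that count, so genes not expressed in the leaf were not separable from genes missed at this depth.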

Other observations

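The tests in this part were chosen after the data were seen, and the results they bear on were known, except the thinning of the deeper cucumber library, the thinning of the mycelium library (set before its value was seen, but after earlier versions of that test), the correlation across an unchanged middle gene and the comparison of neighbours of unlike length, which were set before their values were seen.

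Genes with neighbouring numbers differed together more often than in shuffled orders in both organisms. The correlations below cover the 16381 cucumber and 8767 Botrytis numbered genes past the filter. Genes under the filter were not among them, so neighbours may not have consecutive numbers. Of 349 numbered cucumber genes at least 8-fold higher in the inoculated leaf, 90 (25.8%) had a neighbour in the numbering that was also at least 8-fold higher, against a median of 4.58% and a maximum of 9.74% in 1000 orders shuffled within 10 classes of expression. Of 221 numbered Botrytis genes at least 8-fold higher, 57 (25.8%) had such a neighbour, against a median of 5.43% and a maximum of 13.1%. There were 19 runs of 3 or more consecutive cucumber genes at least 4-fold higher (highest in shuffled orders 6) and 27 runs at least 4-fold lower (highest 21). Botrytis had 13 runs of genes at least 4-fold higher (highest 7) and 0 runs at least 4-fold lower (highest 2). The longest run of higher cucumber genes held 5 genes on chromosome 4, 21.8-fold to 845-fold higher on the log2(RPKM + 1) scale, as are the other folds of runs. The longest run of lower ones held 7 genes on chromosome 7, 4.01-fold to 28.2-fold lower. The longest run of higher Botrytis genes held 5 genes, 4.42-fold to 64.4-fold higher. Runs as long as these also arose in shuffled orders, so it is the number of runs in these 3 sets that lies above every shuffled order, not the length of one.

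The pattern was also seen over all numbered genes: the log2 changes of adjacent genes had a correlation across genes of 0.161 in cucumber (highest of 1000 shuffled orders 0.0282; 0.151 to 0.165 over the settings tried) and 0.163 in Botrytis (highest 0.0494; 0.147 to 0.171), which argues against chance and expression level as the source. Reads running over from one gene into the next stay open: genes 2 numbers apart around a middle gene that changed by under 0.5 (log2) had a correlation of 0.0266 in cucumber and 0.00717 in Botrytis, inside the shuffled range, though unbroken clusters of genes controlled together could give the same value. Without that condition, genes 2 numbers apart had 0.0511 in cucumber (highest shuffled 0.0237) and 0.0503 in Botrytis (0.037), and genes 3 apart had 0.0309 in cucumber (0.0282), all above every shuffled order, and 0.0278 in Botrytis (0.0388), inside the range. Reads shared between neighbouring copies of a gene cannot be told apart from true joint change without sequences; adjacent genes whose lengths differed by over 1.5 times still had correlations of 0.152 and 0.156. Whether Botrytis numbers follow the chromosome is not given in the sources used here, and no biological explanation was tested.

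Large Botrytis changes lay mostly on the higher side, 242 genes at least 8-fold higher against 22 lower, and the shallow inoculated library could hide declines. Earlier versions of the test chose genes by level and differed with that choice: 7 higher and 5 lower among 2430 genes with at least 160 expected reads at their mycelium level, and 145 higher and 5 lower among 3041 genes with at least 160 at the higher level. The mycelium reads were then thinned to the total of the inoculated leaf, and no gene was chosen by its change. Over 100 draws, 266 to 296 genes were at least 8-fold higher and 21 to 42 lower (median 0.112 lower per higher, highest 0.149). This argues against the difference in depth as the whole cause. Only the totals were matched: the thinned mycelium had 1592 to 1677 genes at 0, against 1426 in the inoculated leaf. Cucumber reads assigned to Botrytis genes cannot be told apart from fungal reads without sequences, neither for the 164 numbered genes with no such neighbour nor for the 25.8% with one, where scattered reads would not gather but neighbouring copies could share them. Growth in the leaf, the difference the design names, stays open as untested.

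In cucumber 70.1% of the changed genes were lower, and thinning the deeper library to the shallower total left 70.0%, which argues against depth as the cause. Genes under 4-fold in either direction went from 82.1% to 73.8% of the reads, a log2 change of -0.15 (-0.26 in summed RPKM) against a median of -0.34; a first version that removed only the genes at least 4-fold higher gave -0.37 in reads and -0.51 in summed RPKM, beyond the median. Genes under 2-fold in either direction had a log2 change of their share of -0.07 in reads and -0.17 in summed RPKM. All these versions choose genes by the change under question, and they differ. A larger share of reads in genes that were higher therefore cannot be told apart from other sources of the shift. Whether a single factor moved every gene is not decided by the difference between classes. The median log2 change was lower by 0.49 at 1 to 3 RPKM than at 30 to 100 RPKM (difference -0.49, bootstrap 95% range over genes -0.56 to -0.43). These classes use the mean of both libraries, so each gene's own change helped set its class. The inoculation itself, and the RNA quality of infected tissue, stay open as untested. A plant age was recorded for the leaf alone only, so plant age cannot be told apart from the inoculation.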
